A study of Mus musculus with 9 samples.

How the data were processed

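The data are 9 single-colour Affymetrix mouse gene arrays of total RNA from TS cells, 3 for each of the arrests named G1, S and G2M, with replicate letters A, B and C. Groups and letters were taken from the sample titles. The labels give 1 protocol text for all samples, and the text's arrest at the boundary of G1 and S was taken as that of the samples titled G1. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Mean values are given as mean ± SD over 3 arrays and fold changes as log2 differences, the first-named stage minus the second.

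The deposited values are on the log2 scale, 1 per probe set and array, and were made with RMA in Affymetrix Power Tools, per the submitters' processing notes, which also name R 2.11.1 and the genome build mm9. RMA corrects background, makes the arrays' probe distributions alike by quantile normalization and sums probes by median polish, so differences in total RNA per cell between stages are not kept. No detection p-value and no scanner intensity was used here, so no probe set was called absent, and low values hold mostly background, which shrinks fold changes of dim genes. No coordinates are given, since the table of genes at hand (GRCm38.p6) follows another build than the one named for the arrays and was used for names.

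Of 35518 probe sets, 21780 were paired with exactly 1 gene symbol in the platform annotation, 1605 with several and 12133 with none listed. Genes were named from the first kind alone. Where a gene had several such probe sets (998 genes), the one with the highest mean over the 9 arrays was used, which left 19935 genes. Entrez identifiers of 19853 genes matched the table of current symbols, and no symbol changed. No gene had probe sets called in opposite directions in any of the 3 comparisons.

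Tests were made with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per stage was fitted to all 9 arrays, so that the stages share 1 estimate of the spread per gene, followed by contrasts for S against G1, G2M against S and G2M against G1 and by eBayes moderation. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 19935 genes of a contrast, with a threshold of 0.05, and a moderated F test over the 3 means gave genes changed among the stages. No filter on dim genes was used. The 3 contrasts share arrays, so their calls are not independent of each other.

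In all, 22 gene lists were tested: S phase genes, G2 and M phase genes, G1 to S cyclins and the E2F network, kinetochore and spindle checkpoint, condensin and cohesin, H2A.Z and its deposition complexes, other replacement histone variants, replication-dependent histones, histone chaperones, p53 targets, replication checkpoint and Fanconi genes, tubulins, immediate early genes, FGF and ERK feedback genes, amino acid and unfolded protein response, cholesterol biosynthesis, glycolysis, ribosome biogenesis, trophoblast stem cell genes, differentiated trophoblast genes, fibroblast markers, and embryonic stem cell and endoderm markers. Some genes stand in more than 1 list. Each list was tested in each contrast with camera and its preset correlation of 0.01, adjusted over all 66 tests. Camera with a correlation estimated per list and fry, which asks whether a list's own genes moved in 1 direction on balance, were run beside it. Of 42 camera calls in the main fit, 1 held with the estimated correlation, and fry called 35 of the 66. Counts of members were made from p-values adjusted over all genes and from p-values adjusted over the list alone.

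Genes are named by a fixed rule. For each contrast it takes a fixed set of cell cycle and H2A.Z genes, the 6 largest and 6 smallest changes among called genes whose arrays did not overlap (leaving out predicted genes and replication-dependent histones), and, per list, up to 2 called members with the largest and 2 with the smallest change. The fixed genes Ccnb1 and Cdkn1a had no probe set with a single symbol and are not reported, and 19 of 23 differentiated trophoblast genes and 17 of 18 trophoblast stem cell genes were measured. The groups, tests, lists, naming rule and settings listed next were chosen before the data were examined.

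These settings were the replicate letter as a block, each array left out in turn, only the 2 stages compared in the fit, the mean of a gene's probe sets, every probe set tested by itself, a filter on genes below the median probe set (6.55), centring on array medians, quantile normalization, an intensity trend with a robust prior, array weights, at least a 2-fold change, and limma's treat against a 1.2-fold change. Added after seeing the data were the median of 1027 olfactory receptor genes per array as a covariate (the background covariate), cyclic loess normalization, and a fit without G1 B and S B.

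The script was tested on simulated data for S against G1 with 19935 genes, 200 of them changed, 50 at each fold. It recovered 14% of genes changed 1.25-fold, 74% at 1.5-fold and 100% at 2-fold and at 3-fold, with 7 false calls. With the main axis of differences between arrays of one stage added to the simulation, it recovered 12%, 50%, 94% and 100%, with 1 false call. The comparisons with G2M were not simulated, so these false calls do not speak for them. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.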

Results

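Gene expression was measured in mouse trophoblast stem (TS) cells, the self-renewing precursors of the placental trophoblast, grown in medium with FGF4 and heparin. By the sample titles the cells had been arrested at 3 stages of the cell cycle, with 3 arrays per stage and 9 in all. G2M cells were taken after 7 h in 40 ng/ml nocodazole, which depolymerises microtubules and blocks the mitotic spindle. S cells were washed out of nocodazole and grown for 7 h without drug. They are S cells by title, and the share of them in S phase was not measured. The protocol describes one more arrest, taken here as that of the samples named G1, at the boundary of G1 and S: after nocodazole the cells had 3 h of fresh medium and then 5 h in 5 mM hydroxyurea, which blocks ribonucleotide reductase and stalls DNA replication. The series title concerns the inheritance of H2A.Z, a variant of histone H2A, through the cell cycle, and the arrays give the transcript levels at each stage. Array medians lay between 6.52 and 6.60 on the log2 scale, and any 2 arrays correlated with r between 0.978 and 0.994 over all probe sets. The number of arrays limits the precision of every value.

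The S arrays were the most spread group. Array S B correlated more closely with G2M B (r = 0.992 over probe sets) than with either other S array (highest r = 0.986). The median of 1027 olfactory receptor genes, used as a gauge of background, was 4.21 in S B against 4.38 in S A and 4.39 in S C. It lay between 4.23 and 4.36 in the G1 arrays and between 4.19 and 4.30 in the G2M arrays. Dim genes and bright genes moved apart along with it: from S to G2M the median change was -0.10 log2 over 10567 genes with a mean below 7 and 0.07 over 6139 genes with a mean of 8 or more.

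The first comparison asked which transcripts differed between the S cells and cells held at the G1 arrest. Replication-dependent histone genes, which supply the chromatin of newly made DNA, had the largest median shift of the 22 lists. In S, 27 of 30 rose (28 adjusted over the list alone) and none fell, with a median of 1.47 log2. The linker histone gene H1f5 rose by 3.16 log2 (SE 0.11, adjusted p = 1.86e-07), from 7.35 ± 0.10 in G1 to 10.5 ± 0.22 in S (SD, n = 3). H2ac4, which codes for histone H2A, rose by 2.88 (SE 0.24, adjusted p = 0.000149), and H4f16, a histone H4 gene outside the list, by 1.31 (SE 0.08, adjusted p = 1.41e-05). The list had an adjusted p of 4.06e-50 by camera and of 0.0224 with an estimated correlation. In the main fit it was the only one of 42 list calls over all comparisons that held with it. Near-identical histone copies can share probes, so single copies are uncertain.

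Genes of G2 and M phase were also higher in S than in G1. Of 53 measured, 17 rose and none fell (28 and 2 adjusted over the list alone), with a median of 0.25. Plk1, a mitotic kinase, rose by 0.97 log2 (SE 0.08, adjusted p = 0.000148), Cks2, a subunit of cyclin-dependent kinases, by 0.67 and Ccna2, cyclin A2, by 0.45 (adjusted p = 0.00401 and 0.00917). The list had an adjusted p of 5.96e-10, and an adjusted p of 0.46 with an estimated correlation. Its median was 0.15 without S B, and 0.13 with G1 B and S B both left out (11 higher and 3 lower, adjusted p = 0.049). Of 43 S phase genes, none rose and 1 fell (the same adjusted over the list alone), with a median of -0.03 and a list adjusted p of 0.111. The gene that fell was Cdc6, a helicase loader, with -0.32 (SE 0.06, adjusted p = 0.012), a call that was lost without G1 C or without S A. Pcna, the replication clamp, differed by -0.02 (SE 0.06, adjusted p = 0.906). The S phase list was called lower without G1 B, with a median of -0.05 (adjusted p = 0.00166), without S B, with -0.09 (adjusted p = 0.00025), and with both left out, with -0.12 (adjusted p = 1.83e-06). Array weights also called it lower, with -0.09 (adjusted p = 0.000261), but these weights did not converge and rested mostly on S A among the S arrays. They were 10.4 for S A, 0.18 for S B and 0.47 for S C. Without S C the list median was 0.01 (adjusted p = 0.91).

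Targets of p53 were lower in S than in the hydroxyurea-treated G1 cells. Of 24 measured, 12 fell and none rose (14 and 1 adjusted over the list alone), with a median of -0.33. Ddit4, an inhibitor of mTORC1, had -0.89 log2 (SE 0.07, adjusted p = 7.97e-05), Eda2r, a receptor of the TNF family, -0.86 (SE 0.09, adjusted p = 0.000685) and Btg2, an antiproliferative gene, -0.76 (SE 0.06, adjusted p = 0.000175). The list had an adjusted p of 2e-12, and an adjusted p of 0.177 with an estimated correlation. Trophoblast stem cell genes moved the other way: 10 of 17 rose and none fell (12 and 0 adjusted over the list alone), with a median of 0.42 (adjusted p = 8.18e-15, and adjusted p = 0.176 with an estimated correlation). Id2, an inhibitor of bHLH factors, rose by 0.99 (SE 0.08, adjusted p = 0.000148) and Nr0b1, an orphan nuclear receptor, by 0.98 (SE 0.14, adjusted p = 0.00324). Differentiated trophoblast genes had 1 of 19 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.359). Esx1, with 0.31, and Mmp9, with -0.46, were those 2, and both calls were lost without G1 A or G1 C, among other arrays.

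Outside these lists, the transcription factor genes Zic2 and Zic5 were among the 6 largest increases in S, with 0.97 and 0.96 log2 (SE 0.12, adjusted p = 0.0011 and 0.00145). The 6 largest decreases held P4ha1, a collagen prolyl hydroxylase, with -1.25 (SE 0.08, adjusted p = 1.88e-05), Ephx1, an epoxide hydrolase, with -1.22, and Prl7a1, a placental prolactin-family hormone, with -1.21. They also held Inka1 with -1.20, the Myb-family gene Mybl1 with -1.13 and Slc27a3 with -1.11. Among regulators of the G1 to S transition, 3 of 28 rose and 2 fell (3 and 5 adjusted over the list alone; list adjusted p = 0.869). Myc rose by 0.51 (SE 0.08, adjusted p = 0.0063). Rb1, the retinoblastoma gene, had -0.94 (SE 0.15, adjusted p = 0.00606). Chek2, a checkpoint kinase, had -0.94 (SE 0.12, adjusted p = 0.00177) and was 1 of 2 genes lower, with none higher, among 29 replication checkpoint and Fanconi genes (4 adjusted over the list alone). That list had a median of -0.10 (adjusted p = 0.0026, and adjusted p = 0.597 with an estimated correlation). Its median was -0.05 without S A and -0.18 without S B. Its call was lost without S C, with -0.06 (adjusted p = 0.12), and with the background covariate, with -0.05 (adjusted p = 0.0508).

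Cholesterol biosynthesis genes had 2 of 19 lower and none higher (6 adjusted over the list alone), Msmo1 with -0.68 and Dhcr7 with -0.56, and a median of -0.20, or -0.13 without S C (adjusted p = 1.91e-07, and adjusted p = 0.199 with an estimated correlation). Glycolysis genes had 2 of 11 lower (4 adjusted over the list alone), Pfkl with -0.40 and the glucose transporter Slc2a1 with -0.33, and a median of -0.15 (adjusted p = 3.64e-05, and adjusted p = 0.176 with an estimated correlation). Ribosome biogenesis genes had 5 of 20 higher (11 adjusted over the list alone), led by Polr1b, a subunit of RNA polymerase I, with 0.51, and a median of 0.18 (adjusted p = 1.91e-07, and adjusted p = 0.319 with an estimated correlation). FGF and ERK feedback genes had 3 of 12 higher and 1 lower (7 and 1 adjusted over the list alone), with Spry4 at 0.52 and Il17rd at -0.39, and a median of 0.24 (adjusted p = 0.000103, and adjusted p = 0.277 with an estimated correlation). Immediate early genes had 6 of 23 higher, Myc among them, and 1 lower, which was Btg2 (7 and 1 adjusted over the list alone; median 0.16, adjusted p = 0.00122, and adjusted p = 0.119 with an estimated correlation).

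Other replacement histone variants had 2 of 6 higher (3 adjusted over the list alone), with H2ax, the variant phosphorylated at DNA breaks, at 0.94 (SE 0.10, adjusted p = 0.00074), and a list adjusted p of 0.00702, or an adjusted p of 0.168 with an estimated correlation. Histone chaperones had 1 of 16 higher, Atrx with 0.33 (5 adjusted over the list alone; adjusted p = 0.00748, and adjusted p = 0.556 with an estimated correlation). That list call was lost without G1 B (adjusted p = 0.099) or S B (adjusted p = 0.256), and that of Atrx without any array but G2M C. Kinetochore genes had 2 of 26 higher, Cenpf with 0.48 and Cdca8 with 0.40, and 1 lower, Spc25 with -0.37 (the same adjusted over the list alone; adjusted p = 0.0439, and adjusted p = 0.734 with an estimated correlation). The list call was lost without G1 B (adjusted p = 0.472), S B (0.887) or G2M A (0.0528), and with G1 B and S B both left out the median turned to -0.0011. That fit also ended the list calls of other variants (adjusted p = 0.099) and chaperones (adjusted p = 0.765). The calls of Cenpf and Cdca8 were lost without G1 A or G1 B, that of Cdca8 also without G1 C or S A, and that of Spc25 without any array but G1 B, S B and G2M A. Amino acid and unfolded protein response genes had 4 of 18 lower (6 lower and 2 higher adjusted over the list alone), with Sesn2 at -0.50. Their median was 0.003 and their mean -0.09 (adjusted p = 0.0439, and adjusted p = 0.468 with an estimated correlation), and leaving out any array but G1 B, S B and G2M B ended the call (adjusted p from 0.0513 to 0.118). The median of that list lay between -0.04 without G1 B and 0.01 without G1 A. Condensin and cohesin genes had 2 of 23 higher (4 higher and 1 lower adjusted over the list alone; list adjusted p = 0.189). That list was called higher without G1 C, with a median of 0.08 (adjusted p = 0.0151), without S C, with 0.12 (adjusted p = 0.0055), and with the background covariate, with 0.12 (adjusted p = 0.00722). In the covariate fit its adjusted p was 0.488 with an estimated correlation. Embryonic stem cell and endoderm markers had 1 of 14 higher, Zfp42 with 0.62 (1 adjusted over the list alone; list adjusted p = 0.197, or 0.0275 with G1 B and S B both left out). No tubulin gene of 16 and no fibroblast marker of 17 passed by limma, also adjusted over the list alone (list adjusted p = 0.831 and 0.916), with 2 tubulins and 1 fibroblast marker at an unadjusted p under 0.05.

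In total, 372 genes were higher and 745 lower in S than in G1 among 19935 tested, of which 20 and 13 differed by at least 2-fold, and 3573 had an unadjusted p under 0.05. In 21.8% of all genes the 3 arrays of one stage lay above the 3 of the other, where chance gives 10% on average. Genes move together between arrays, so the share of a single grouping can depart from that average without an effect of the stage. The counts ranged from 140 higher and 359 lower without G1 A to 466 and 1167 without S B, and were 1630 and 1485 with the background gauge as a covariate.

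The second comparison asked which transcripts differed between cells held in nocodazole and the S cells. Genes of G2 and M phase were higher in G2M: 34 of 53 rose and none fell (44 and 0 adjusted over the list alone), with a median of 0.39 log2. Gas2l3, a cytoskeletal linker protein, rose by 0.86 (SE 0.09, adjusted p = 0.00051), Cenpe, a kinetochore motor, by 0.71 (SE 0.12, adjusted p = 0.00783) and Plk1 by 0.45 (SE 0.08, adjusted p = 0.00806). The list had an adjusted p of 1.5e-26, and an adjusted p of 0.238 with an estimated correlation. Condensin and cohesin genes had 7 of 23 higher and none lower (14 and 0 adjusted over the list alone), led by Sgo2a, a guardian of centromeric cohesion, with 0.59 (SE 0.10, adjusted p = 0.00577). Their median was 0.28 (adjusted p = 6.16e-10, and adjusted p = 0.337 with an estimated correlation) and was 0.15 with the background covariate. Kinetochore and spindle checkpoint genes had 10 of 26 higher (13 higher and 1 lower adjusted over the list alone), with a median of 0.22 (adjusted p = 3.32e-08, and adjusted p = 0.337 with an estimated correlation), or 0.13 with that covariate.

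Replication-dependent histones were lower in G2M than in S in 14 of 30 genes and higher in none (19 and 0 adjusted over the list alone), with a median of -0.36 (adjusted p = 3.27e-10, and adjusted p = 0.16 with an estimated correlation). H2bc14, a histone H2B gene, had -0.89 log2 (SE 0.08, adjusted p = 0.000155) and H1f5 -0.76 (SE 0.11, adjusted p = 0.00272). Other replacement histone variants had 1 of 6 higher and 1 lower (the same adjusted over the list alone; list adjusted p = 0.69): Cenpa, the histone H3 of centromeres, rose by 0.51 (SE 0.06, adjusted p = 0.00105), and H2ax had -0.62 (SE 0.10, adjusted p = 0.00621). Cyclin D1, Ccnd1, had -0.89 (SE 0.07, adjusted p = 0.000155) and Cdkn1c, a cyclin-dependent kinase inhibitor, -1.51 (SE 0.06, adjusted p = 3.1e-06). The G1 to S list that holds both had 3 of 28 higher and 3 lower (5 and 3 adjusted over the list alone; list adjusted p = 0.437).

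FGF and ERK feedback genes, which include inhibitors of receptor tyrosine kinase signalling, were higher in G2M in 10 of 12 cases and lower in none (10 and 1 adjusted over the list alone), with a median of 0.42 (adjusted p = 3.92e-10, and adjusted p = 0.143 with an estimated correlation). Spry4 rose by 0.94 (SE 0.09, adjusted p = 0.000247) and Spred1 by 0.76 (SE 0.10, adjusted p = 0.00235). Differentiated trophoblast genes had 8 of 19 lower and 1 higher (9 and 1 adjusted over the list alone), with a median of -0.27 (adjusted p = 3.55e-05, and adjusted p = 0.0527 with an estimated correlation). That median was -0.18 with the background covariate and -0.17 with cyclic loess normalization. Phlda2, an imprinted gene that restrains placental growth, had -1.30 (SE 0.06, adjusted p = 5.29e-06), and Flt1, a VEGF receptor, was the 1 that rose, by 0.59 (SE 0.06, adjusted p = 0.000495). Trophoblast stem cell genes went both ways, with 3 of 17 higher and 3 lower (4 and 5 adjusted over the list alone; list adjusted p = 0.573). Nr0b1 rose by 1.83 (SE 0.14, adjusted p = 0.000114). Tfap2c and Ets2, transcription factors that differentiated trophoblast also uses, had -0.50 and -0.46 (adjusted p = 0.00231 and 0.00572).

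The 6 largest increases from S to G2M were Nr0b1, Mboat2 with 1.53, Bex4 with 1.28, Upp1, a uridine phosphorylase, with 1.27, Pgap1 with 1.25 and Cyp26a1, which degrades retinoic acid, with 1.18 log2. Their highest adjusted p was 0.00677, that of Bex4. The 6 largest decreases were Prl7a1 with -1.80, Serpinb9d with -1.64, Cdh5, VE-cadherin, with -1.56, the homeobox gene Rhox6 with -1.55, Plac1, a placental gene, with -1.53, and Cdkn1c, and their highest adjusted p was 0.000756, that of Prl7a1.

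Smaller shifts between G2M and S came with the background gauge, which was lower in all 3 G2M arrays than in S A and S C. Cholesterol biosynthesis genes had 4 of 19 higher (6 adjusted over the list alone; median 0.20, adjusted p = 7.97e-06, and adjusted p = 0.267 with an estimated correlation). Cyp51, a lanosterol demethylase, led with 0.73, a call lost without S A, S C, G2M B or G2M C. The list median was 0.10 with the background covariate, where camera still called the list (adjusted p = 0.000856, and adjusted p = 0.137 with an estimated correlation). Replication checkpoint and Fanconi genes had 4 of 29 higher (7 higher and 1 lower adjusted over the list alone), with Fancm at 0.73 and a median of 0.15 (adjusted p = 0.000179, and adjusted p = 0.532 with an estimated correlation), or 0.04 with the covariate (adjusted p = 0.223). That median was 0.25 without S B and 0.09 without S C. Histone chaperones had 2 of 16 higher (3 adjusted over the list alone), Atrx with 0.55 and Nap1l1 with 0.54, the latter lost without S A, S C, G2M B or G2M C (list adjusted p = 0.000826, adjusted p = 0.468 with an estimated correlation and adjusted p = 0.0815 with the covariate). S phase genes had 1 of 43 higher, Hells with 0.51, lost without the same 4 arrays (1 adjusted over the list alone; median 0.07, adjusted p = 0.000937, and adjusted p = 0.615 with an estimated correlation), and with the covariate the median turned to -0.0060 (adjusted p = 0.838). It was 0.14 without S B and 0.04 without S A, S C or G2M C. Ribosome biogenesis genes had none of 20 passing by limma, also adjusted over the list alone, and 3 at an unadjusted p under 0.05 (median 0.09, adjusted p = 0.0137, and adjusted p = 0.593 with an estimated correlation). Their list call was lost without S C, with 0.04 (adjusted p = 0.1), and with the covariate, with 0.03 (adjusted p = 0.546). It was lost too with cyclic loess normalization (adjusted p = 0.991), where the list test pointed downward. Cyclic loess also ended the list calls of S phase genes (adjusted p = 0.503), chaperones (0.141) and fibroblast markers (0.221), and quantile normalization those of S phase genes and fibroblast markers (0.129 each) and ribosome biogenesis (0.4). Leaving out dim genes ended those of S phase genes (0.108), checkpoint genes (0.0519), ribosome biogenesis (0.209) and fibroblast markers (0.0766).

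Of the remaining lists, immediate early genes had 6 of 23 lower in G2M (8 lower and 1 higher adjusted over the list alone), with Fosb at -0.79 and Fosl1 at -0.53 (list adjusted p = 0.0135, and adjusted p = 0.168 with an estimated correlation). That call was lost without S B (adjusted p = 0.098). Amino acid and unfolded protein response genes had 3 of 18 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0182, adjusted p = 0.384 with an estimated correlation, adjusted p = 0.138 with the covariate, 0.0678 with quantile normalization, 0.229 with cyclic loess and 0.182 with dim genes left out). Fibroblast markers had 2 of 17 lower, also adjusted over the list alone, of which Twist2 had -0.57 (adjusted p = 0.0298, and adjusted p = 0.563 with an estimated correlation). Their median of -0.16 became -0.0061 with the covariate (adjusted p = 0.772), and the call was lost without S A (adjusted p = 0.0744), S C (0.0858) or G2M C (0.0998). That median was -0.08 without S A or without G2M C, -0.11 without S C and -0.25 without S B. Tubulin genes had 2 of 16 lower, also adjusted over the list alone, Tubb3 with -0.86 and Tubb6 with -0.38 (list adjusted p = 0.14 by camera and 0.00124 by fry), the call of the latter lost without G2M C. Camera called that list lower with dim genes left out (adjusted p = 0.0471) and with cyclic loess (adjusted p = 0.0397). Targets of p53 had 2 of 24 higher and 2 lower (the same adjusted over the list alone; list adjusted p = 0.168), with Sfn at -0.64 and Plk3 at -0.53. That list was called higher without S B, with a median of 0.11 (adjusted p = 0.044). Glycolysis genes had 1 of 11 higher, Pfkl (1 higher and 1 lower adjusted over the list alone; list adjusted p = 0.115), a call lost without S A, S C, G2M B or G2M C. Embryonic stem cell and endoderm markers had 1 of 14 lower, Pdgfra with -0.37 (1 adjusted over the list alone; list adjusted p = 0.267), a call lost without any array but G1 B and S B.

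In total, 811 genes were higher and 722 lower in G2M than in S, of which 12 and 24 differed by at least 2-fold, and 4888 had an unadjusted p under 0.05. In 27.1% of all genes the arrays of both stages did not overlap, where chance gives 10% on average, with the same limit as for S against G1. The counts ranged from 254 higher and 325 lower without G2M C to 2322 and 2094 without S B, and were 866 and 467 with arrays centred on their medians and 822 and 1220 with the background covariate.

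The third comparison set the nocodazole arrest against the G1 arrest. Genes of G2 and M phase were higher in G2M in 46 of 53 cases and lower in 1 (47 and 1 adjusted over the list alone), with a median of 0.60 log2. The gene that fell was Psrc1, a spindle protein, with -0.30, a call lost without G1 A, G1 C, G2M B or G2M C. Plk1 rose by 1.42 (SE 0.08, adjusted p = 3.95e-06), from 9.03 ± 0.10 to 10.4 ± 0.02 (SD, n = 3), Cks2 by 1.25 (SE 0.10, adjusted p = 2.83e-05) and Ccna2 by 0.77 (SE 0.08, adjusted p = 0.000129). The list had an adjusted p of 1.49e-30, and an adjusted p of 0.199 with an estimated correlation. Cdk1, a fixed gene of this list, passed in no comparison. It had 0.18 from G1 to S, -0.09 from S to G2M and 0.08 from G1 to G2M. Kinetochore genes had 13 of 26 higher (16 higher and 1 lower adjusted over the list alone), with Cenpf at 0.99 and a median of 0.35 (adjusted p = 2.71e-08, and adjusted p = 0.337 with an estimated correlation). Condensin and cohesin genes had 14 of 23 higher (16 adjusted over the list alone). Sgo2a had 1.08 and the separase gene Espl1 0.75, and the list median was 0.37 (adjusted p = 5.69e-09, and adjusted p = 0.349 with an estimated correlation).

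H2az1, which codes for H2A.Z.1, rose from 11.3 ± 0.06 in G1 to 11.6 ± 0.07 in G2M (SD, n = 3), a log2 change of 0.37 (SE 0.08, adjusted p = 0.00773). Its changes from G1 to S, 0.19 (SE 0.08, adjusted p = 0.207), and from S to G2M, 0.18 (SE 0.08, adjusted p = 0.193), did not pass, though the latter was 0.23 without S B (adjusted p = 0.0469). H2az2, the second H2A.Z gene, differed by 0.09 between G2M and G1 (SE 0.08, adjusted p = 0.525), by -0.04 between S and G1 (adjusted p = 0.868) and by 0.13 between G2M and S (adjusted p = 0.332). Of 23 genes for H2A.Z and its deposition complexes, 12 rose from G1 to G2M and none fell (14 and 0 adjusted over the list alone), with a median of 0.27 (adjusted p = 1.91e-07, and adjusted p = 0.349 with an estimated correlation). Besides the H2A.Z genes, this list held subunits of the SRCAP, TIP60 and INO80 complexes and Anp32e, which also stands in the G2 and M phase list. Its shift therefore cannot be assigned to deposition alone. Actr6, a subunit of the SRCAP complex, had 0.68 (SE 0.17, adjusted p = 0.0165) and Ino80, an ATPase that remodels H2A.Z nucleosomes, 0.42 (SE 0.11, adjusted p = 0.0288). Both calls were lost without G1 B, G2M B or G2M C, and that of Ino80 also without G1 A or G2M A. From G1 to S, 1 of these 23 genes rose, the acetyltransferase Kat5 with 0.33 (3 adjusted over the list alone; list adjusted p = 0.00161, and adjusted p = 0.563 with an estimated correlation), a gene call lost without G1 A, G1 B or S A. The list median was 0.11, or 0.18 without G1 C and 0.17 without S C. The list call was lost without G1 B, with 0.06 (adjusted p = 0.0524), and without S B, with 0.02 (adjusted p = 0.249), and with both left out the median was -0.0015. From S to G2M 1 gene rose, Ep400 with 0.31 (0 adjusted over the list alone; list adjusted p = 0.000304, adjusted p = 0.523 with an estimated correlation, adjusted p = 0.206 with the background covariate and 0.0618 with cyclic loess). The Ep400 call was lost without any array but S B.

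Replication-dependent histones were higher in G2M than in G1 in 24 of 30 genes and lower in none (28 and 0 adjusted over the list alone), with a median of 1.18 (adjusted p = 1.87e-26, and adjusted p = 0.0507 with an estimated correlation). H1f5 rose by 2.40 log2 (SE 0.11, adjusted p = 9.85e-07) and H2ac4 by 2.27 (SE 0.24, adjusted p = 0.00013). Cenpa, with 0.77 (SE 0.06, adjusted p = 2.46e-05), was the 1 of 6 other replacement variants that rose (2 adjusted over the list alone; list adjusted p = 0.0137, adjusted p = 0.176 with an estimated correlation and 0.0885 with dim genes left out). Histone chaperones had 7 of 16 higher (11 adjusted over the list alone), with a median of 0.25. Atrx, a partner of the chaperone Daxx, had 0.88 and Nasp, a chaperone of histones H1 and H3, 0.60 (list adjusted p = 3.26e-06, and adjusted p = 0.337 with an estimated correlation). Ribosome biogenesis genes had 13 of 20 higher (14 adjusted over the list alone), with Polr1b at 0.65 and a median of 0.24 (adjusted p = 8.35e-09, and adjusted p = 0.277 with an estimated correlation). With cyclic loess normalization the medians of chaperones and ribosome biogenesis were 0.16 and 0.14.

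**Figure D1:**
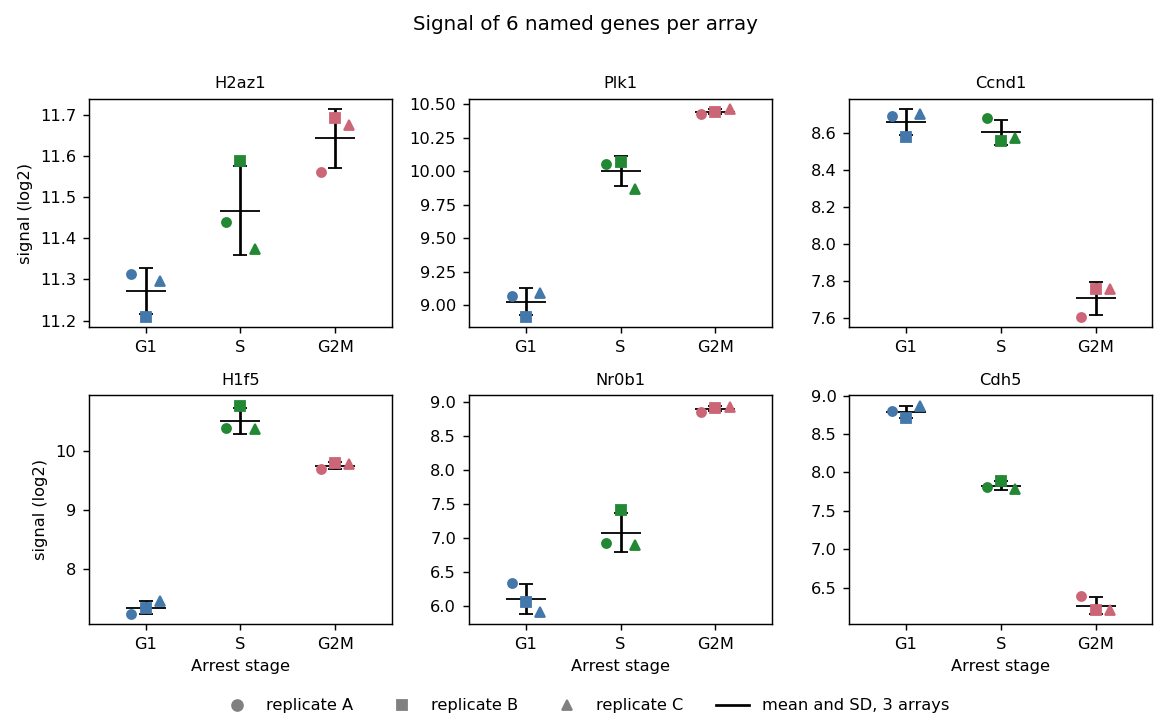
Signal of H2az1, Plk1, Ccnd1, H1f5, Nr0b1 and Cdh5 (vertical axis, log2, with its own range in each panel) on the 9 arrays by arrest stage (horizontal axis), with replicates as symbols and the mean and SD of 3 arrays as bars. H2az1 rose by 0.37 log2 and Plk1 by 1.42 from G1 to G2M, and Ccnd1 and Cdh5 were lowest in G2M, with changes of -0.95 and -2.52 against G1.

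Trophoblast stem cell genes were higher in G2M than in G1 in 12 of 17 cases and lower in 3 (the same adjusted over the list alone), with a median of 0.45 (adjusted p = 1.46e-07, and adjusted p = 0.319 with an estimated correlation). Nr0b1 rose by 2.81 log2 (SE 0.14, adjusted p = 2.34e-06), from 6.10 ± 0.22 to 8.90 ± 0.04 (SD, n = 3), and Id2 by 1.19 (SE 0.08, adjusted p = 9.82e-06), while Gata3 and Tfap2c had -0.39 and -0.38. Differentiated trophoblast genes had 11 of 19 lower and 1 higher (the same adjusted over the list alone), with a median of -0.42 (adjusted p = 9.1e-06, and adjusted p = 0.0507 with an estimated correlation). Cdkn1c had -1.62 (SE 0.06, adjusted p = 7.69e-07) and Phlda2 -1.17 (SE 0.06, adjusted p = 3.71e-06), and Flt1 rose by 0.59 (SE 0.06, adjusted p = 0.000133). FGF and ERK feedback genes had 9 of 12 higher and none lower (10 and 0 adjusted over the list alone), with a median of 0.78 (adjusted p = 2.6e-10, and adjusted p = 0.143 with an estimated correlation), led by Spry4 with 1.46 (SE 0.09, adjusted p = 5.09e-06) and Spred1 with 1.17 (SE 0.10, adjusted p = 5.37e-05).

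The 6 largest increases from G1 to G2M were Nr0b1, Zic2 with 1.96, Cyp26a1 with 1.79, the LIM-domain gene Lmo4 with 1.73, Pgap1 with 1.65 and Zic5 with 1.62 log2, and their highest adjusted p was 2.76e-05, that of Pgap1. The 6 largest decreases held Prl7a1 with -3.00, Cdh5 with -2.52, the adhesion receptor Adgrf5 with -2.15, and the glutamine transporter Slc38a3 with -2.15. They also held Pecam1, an adhesion molecule, with -2.13 and the prolactin-family gene Prl2c5 with -1.95, and their highest adjusted p was 0.000139, that of Prl2c5. Targets of p53 had 15 of 24 lower and 1 higher (16 and 1 adjusted over the list alone). Ddit4 had -0.87, Btg2 -0.82 and Gadd45a, the one that rose, 0.47, and the list median was -0.30 (adjusted p = 3.55e-07, and adjusted p = 0.319 with an estimated correlation).

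Camera made no call from G1 to G2M for 10 lists, of which fry called tubulins (adjusted p = 0.00276) and glycolysis genes (adjusted p = 0.00253), both downward. S phase genes had 4 of 43 higher and 2 lower (3 and 2 adjusted over the list alone; list adjusted p = 0.172), with Hells, a chromatin remodeller, at 0.64 and Nasp at 0.60. The S phase list was called higher without G1 C, with a median of 0.08 (adjusted p = 0.0305). Regulators of the G1 to S transition had 6 of 28 higher and 4 lower (7 and 5 adjusted over the list alone; list adjusted p = 0.825), with Cdkn1b, the inhibitor p27, at 0.61 and Ccnd1 at -0.95 (SE 0.07, adjusted p = 2.32e-05). Replication checkpoint and Fanconi genes had 4 of 29 higher and 1 lower (4 and 2 adjusted over the list alone; list adjusted p = 0.605), with Fancm at 0.84 and Chek2 at -0.57. Tubulin genes had 2 of 16 lower, also adjusted over the list alone, Tubb3 with -1.19 and Tubb6 with -0.44 (list adjusted p = 0.451). Immediate early genes had 4 of 23 higher and 5 lower (5 and 6 adjusted over the list alone; list adjusted p = 0.793), and amino acid and unfolded protein response genes 2 of 18 each way, also adjusted over the list alone (list adjusted p = 0.923). Cholesterol biosynthesis genes had 4 of 19 lower and glycolysis genes 3 of 11, both also adjusted over the list alone (list adjusted p = 0.869 and 0.0649). Glycolysis was called lower without G1 B, with a median of -0.12 (adjusted p = 0.035), and with quantile normalization (adjusted p = 0.00131) and cyclic loess (adjusted p = 0.000141), among other settings. Fibroblast markers had 3 of 17 lower (4 adjusted over the list alone; median -0.10, list adjusted p = 0.0723) and were called lower without G1 A, with a median of -0.15, or G2M A, with -0.20 (adjusted p = 0.0265 each). Their median was -0.04 with G1 B and S B both left out (adjusted p = 0.22) and -0.0038 with the background covariate (adjusted p = 0.395). Among embryonic stem cell and endoderm markers, 1 of 14 passed each way, also adjusted over the list alone (list adjusted p = 0.863).

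**Figure D2:**
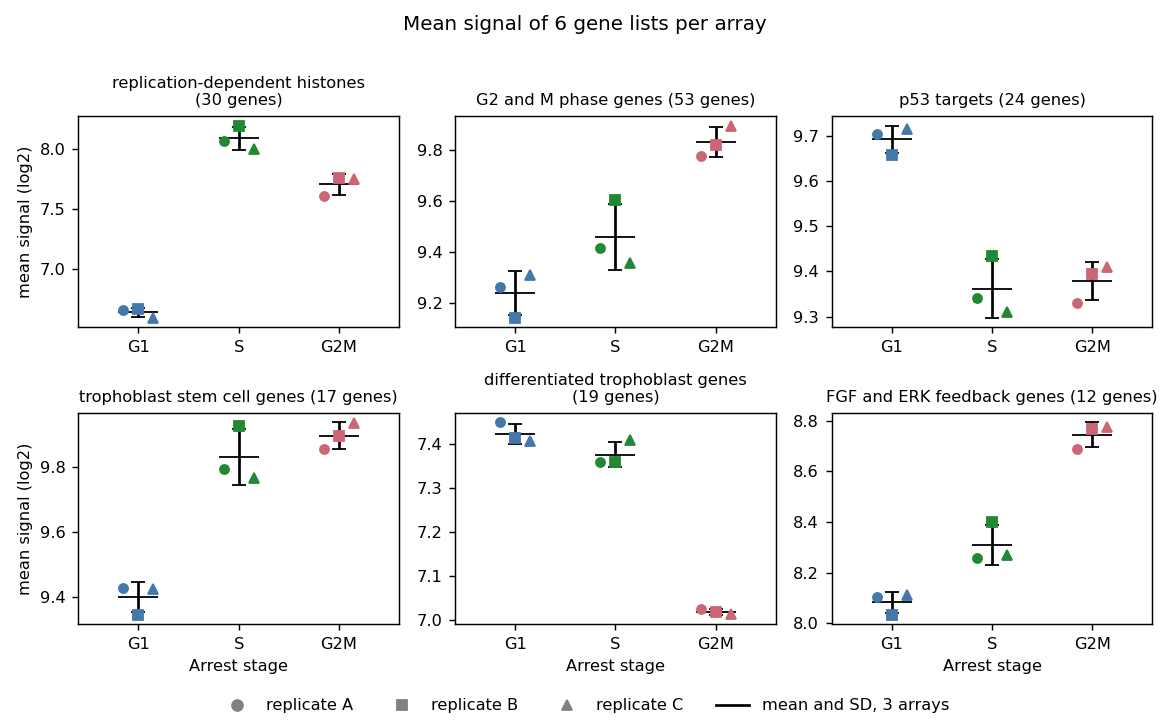
Mean signal of 6 gene lists (vertical axis, log2, with its own range in each panel) on the 9 arrays by arrest stage (horizontal axis), with replicates as symbols and the mean and SD of 3 arrays as bars. The median shift of replication-dependent histones was 1.47 log2 from G1 to S, and differentiated trophoblast genes were lowest in G2M, with a median shift of -0.42 against G1.

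In total, 1814 genes were higher and 1726 lower in G2M than in G1, of which 73 and 82 differed by at least 2-fold, and 5862 had an unadjusted p under 0.05. In 38.0% of all genes the arrays of both stages did not overlap, where chance gives 10% on average, again with that limit. The count of higher genes ranged from 975 without G2M C to 2437 without S B, and that of lower genes from 1186 without G1 A to 2143 without S B. With arrays centred on their medians, 2002 were higher and 1303 lower.

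Across the 3 stages, 3441 genes changed by limma's moderated F test. Of these, 1433 had their highest mean in G1, 491 in S and 1517 in G2M, while of all 19935 genes tested 6252 were highest in G1, 8005 in S and 5678 in G2M. The histone genes H1f5 and H2bc14 were highest in S, Plk1, Nr0b1 and Spry4 in G2M, and Ddit4, Cdh5 and Cdkn1c in G1. The count was 2000 without G2M B and 5860 without S B. Among other fixed genes, Ccne1 rose by 0.31 log2 from G1 to S, a call lost without S A, S C or any G1 array. Ccne2 had -0.44 from G1 to G2M, a call lost without G1 A, G1 C or any G2M array. From G1 to S it had -0.47, called only without G1 B or without S B. Cdt1, Gmnn and Pcna passed in no comparison, though Gmnn was called from S to G2M without S B, with 0.33 (limma adjusted p = 0.0249).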

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

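Of the gene list results under other settings, 1259 kept their side of the threshold, 98 lost their call, 25 gained one and 4 turned. Of those for named genes, 3636 kept their side, 391 lost a call, 24 gained one and none turned. A change of direction counted as a turn only if the result was called in the main fit or under the other setting. Uncalled results could change direction and still count as kept. Pcna from G1 to S, for example, had -0.024 in the main fit and up to 0.0033 with 1 array left out. With 1 array left out at a time, 34 of 42 list calls and 123 of 171 calls of named genes were kept throughout. Where no cause is named below, the cause was not tested.

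With 1 array left out at a time, S against G1 gave 140 to 466 genes higher and 359 to 1167 lower, G2M against S 254 to 2322 and 325 to 2094, and G2M against G1 975 to 2437 and 1186 to 2143. The 3 stages together gave 2000 to 5860 genes, and list calls numbered 39 to 43. Every highest gene count came without S B, the array nearest to another stage by correlation over all probe sets.

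With the replicate letter as a block (paired), S against G1 gave 141 higher and 398 lower, G2M against S 314 and 358, G2M against G1 1175 higher, and the 3 stages 2037. Deviations from stage means of arrays of one letter correlated with r from -0.64 to 0.41 over 9 pairs. With only the 2 stages compared in the fit, S against G1 gave 162 and 449 and G2M against S 412 and 418, but G2M against G1 2180 and 1978. Asking for a 2-fold change by construction leaves fewer genes, 20 and 13, 12 and 24, 73 and 82 in the same order of comparisons and 168 over the 3 stages. So does treat against a 1.2-fold change, with 38 and 97, 56 and 91, 305 and 399.

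Without dim genes, fewer genes were tested and 674 were higher in S than in G1 and 1364 higher in G2M than in S. With an intensity trend and robust prior these were 615 and 1271. Centring on array medians gave 467 genes lower in G2M than in S. Quantile normalization gave 804 higher and 1168 lower in S than in G1 and 1188 lower in G2M than in S. Array weights gave 5238 and 3735, 5233 and 8012, 3786 and 4099, and 15034 over the 3 stages, but their estimate stopped before convergence and put nearly all weight on a few arrays. With an estimated correlation in the main fit, 1 list call of 42 was left.

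Chosen after seeing the data were 3 settings. The background covariate gave 1630 and 1485 for S against G1, 1220 lower in G2M than in S and 5445 over the 3 stages. With that covariate and an estimated correlation, camera called replication-dependent histones and trophoblast stem cell genes from G1 to S. It also called FGF and ERK feedback genes from S to G2M and from G1 to G2M (adjusted p = 0.0339 for each of these calls). Cyclic loess normalization gave 707 and 1224 for S against G1 and 1140 lower in G2M than in S. Leaving out G1 B and S B gave 850 and 1471 for S against G1, 2701 and 2831 for G2M against S and 6313 over the 3 stages. Counted as turned were kinetochore genes from G1 to S under array weights, with 0.0017 and a downward list test (adjusted p = 0.901). So were kinetochore genes from G1 to S without G1 B and S B, with -0.0011 (adjusted p = 0.425). S phase genes from S to G2M were counted with the background covariate, with -0.0060 (adjusted p = 0.838). The last was ribosome biogenesis from S to G2M with cyclic loess normalization. Its median was 0.021 and its list test pointed downward (adjusted p = 0.991). Signal near background limits what dim genes can show.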

Other observations

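The gene groups here, and the tests of them, were chosen after results were seen. The exceptions are the median of the general endothelial markers and the median from G1 to S of the hypoxia response genes, whose bounds were set down before those values were seen. Members of the Serpinb9 family, protease inhibitors of which several are placental, were lower in G2M than in S in 5 of 5 genes measured, with a median of -1.26 log2. Of 8 genes of the Rhox homeobox family, 3 were lower in G2M than in S, with a median of -0.26, or -0.14 with the background covariate. Rhox6 had -1.55, Rhox9 -1.46 and Rhox12 -0.73. Among 23 imprinted genes, 4 were higher and 10 lower in G2M than in G1, with a median of -0.20. Mest and Peg3 rose by 0.88 and 0.75, and Cdkn1c, Phlda2 and Peg10 had -1.62, -1.17 and -0.49. These families were picked because members such as Serpinb9d, Rhox6 and Cdkn1c stood out in the same comparisons, so no list test is given.

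Of 25 genes that respond to low oxygen, 11 were lower in S than in the hydroxyurea-treated G1 arrays and none higher. P4ha1 had -1.25 log2, Plod2, a collagen lysyl hydroxylase, -1.08 and Bnip3, a mitophagy receptor, -0.83. From S to G2M, 9 were higher and 3 lower, with Bnip3 at 0.98, Pdk1, which restrains pyruvate dehydrogenase, at 0.85 and Adm, adrenomedullin, at -0.92. The 22 genes other than P4ha1, Plod2 and Bnip3, which had drawn attention to the group, had a median of -0.21 from G1 to S, with 8 lower and none higher by limma (adjusted p = 3.96e-07, and adjusted p = 0.125 with an estimated correlation). From G1 to G2M, a comparison added after the first, they had a median of -0.07, with 5 higher and 7 lower (adjusted p = 0.123), and all 25 had -0.10 (adjusted p = 0.0451, and adjusted p = 0.413 with an estimated correlation). A hypoxia-like response in the G1 arrays and a low level in S therefore cannot be told apart, and neither oxygen nor culture density was measured.

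Dim and bright genes moved apart between arrays of one stage, most of all between S B and the other S arrays. The first axis of bright genes within stages correlated in size with the median of olfactory receptor genes over the 9 arrays, both as deviations from stage means. Pearson's r was 0.972 (exact permutation p = 0.00016) and Spearman's rho 0.917 (exact permutation p = 0.00131), and r was 0.94 without S B and G1 C (exact permutation p = 0.00556, n = 7). It was not the only such relation computed. Over the 9 arrays the olfactory receptor median had r = -0.977 with the SD over genes. Over genes, mean signal had rho = -0.56 with the loading on the within-stage axis. The permutation p-values are not adjusted for this choice. Deviations from a shared mean are not fully independent. A batch shared by all arrays of a replicate letter is argued against by correlations between arrays of one letter from -0.64 to 0.41, though one shared by some pairs stays open, and an exchange of the labels of G1 B and S B by the histone mean of S B, which lay 1.52 log2 above the highest G1 array. Olfactory receptor genes are dim, so their relation to the bright genes largely restates that dim and bright genes moved apart. A difference in signal range between arrays may account for the pattern but was not tested independently, and what produced it stays open.

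Replication-dependent histone genes were low in the G1 arrays. A difference in signal range is argued against by the list median of 1.49 log2 with the background covariate. Probes shared between near-identical core histone copies are argued against as the whole source by 4 linker histone genes, with a median of 2.33 from G1 to S. Those genes do not tell how many core copies were measured separately. Fewer cells expressing replication genes in G1 would lower other S phase genes too, but 16 such genes outside the fixed list had a median of -0.044 (SD 0.14). These transcripts do not tell how many cells were making DNA, which was not measured, so a difference in that share stays open. Hydroxyurea itself and the stage cannot be told apart, since 0 G1 arrays were made without it, and hours since the start of nocodazole (15, 14 and 7 for G1, S and G2M) also differ with the stage.

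Differentiated trophoblast markers were lowest in the G2M arrays. Stem cell genes were instead low in the G1 arrays, with medians of 0.42 log2 from G1 to S and 0.45 from G1 to G2M. From S to G2M their median was 0.01 (camera adjusted p = 0.573), so the lists did not move together. For the differentiated markers, a difference in signal range is argued against as the whole source by their median from G1 to G2M with the background covariate, -0.35. From S to G2M, though, the covariate took their median from -0.27 to -0.18. Of 12 general endothelial markers, 3 were lower in G2M than in G1 and none higher (median -0.19, adjusted p = 0.0166, and adjusted p = 0.275 with an estimated correlation), and their mean was 6.46 to 6.62 on the G1 arrays and 6.19 to 6.33 on the G2M arrays. That median argues against endothelial cells in the G1 arrays as the whole source of the changes of Cdh5 and Pecam1, -2.52 and -2.13, as do the 2 markers with a mean of 7 or more, looked at only afterwards, Kdr with 0.28 and Plvap with -0.50, but the others lie nearer background and a small share of such cells stays open. A lower share of differentiated cells in G2M cannot be told apart from regulation within cells: of 10 markers with a mean of 7 or more, 6 were lower and 1, Flt1, higher, from -1.62 to 0.59, and the shorter time since the start of nocodazole stays open and untested.

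Other splits of the same arrays were run for each count of genes. The 10 splits of 6 arrays are too few for a share under 0.05: as many genes as the real one were called by 1 split, the real one, in each comparison, with 1117 genes for S against G1 (highest other 256), 1533 for G2M against S (highest other 1184) and 3540 for G2M against G1 (highest other 0). Over the 3 stages, 3 of 100 splits drawn, the real one included, called at least 3441 genes. That share is under 0.05 among the splits drawn, but not all splits were drawn and others than the real one reached its count. Chance is therefore not excluded by it. The highest other count, 4763, came from a split that kept the G2M arrays together and put S B with G1 A and G1 C, which points to the structure of the arrays described above.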
